A study of Homo sapiens with 2 samples.

How the data were processed

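The data were spatial transcriptomes of 2 sections of human endomyocardial biopsy tissue fixed in formalin and embedded in paraffin, 1 labelled as before and 1 as after rilonacept. Per the labels' protocols, sections of 10 µm were cut and libraries were made on the 10x Genomics Visium platform with the CytAssist instrument, which captures gene-specific probes, rather than whole transcripts, on a grid of barcoded spots. A spot covers a small region that can hold several cells of different types. Per the file headers, the deposited matrices were written by Space Ranger 3.0.0 and hold raw counts of unique molecular identifiers (UMIs) per gene and spot, for spots under and outside the tissue. The submitters' processing notes also name Space Ranger. The genome build, the probe set and the way tissue was marked were not given in the sources used here. Gene symbols were taken as the deposited matrices pair them with identifiers, so no coordinates are given.

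The matrices listed 37082 features, of which 18932 were detected in at least 1 section. Features marked as deprecated (481 of the 37082) took 0.641% of UMIs before and 0.631% after; they counted toward totals but were not analysed as genes. Features sharing a symbol (6 of those left) were set aside, as were 12 detected genes whose level can reveal a person's sex or an inherited deletion or allele. This left 18447 genes. In-tissue spots with at least 200 UMIs were kept, which removed 9 of 806 spots before and 0 of 1277 after. No doublet caller was run, because spots are not cells.

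With 1 sample per group no test between groups was possible, and no p-value, standard error or count of changed genes was made from spots. Counts were summed over the spots of a section and given as counts per 1000000 UMIs of those spots (CPM), for a list as the sum over its members. A gene's ratio, after over before, carried a prior count of 0.5 and an exact 95% Clopper-Pearson interval conditional on the sum of both counts. Genes with at least 20 CPM in at least 1 section were counted as higher or lower when the ratio was at least 2-fold and the interval lay on that side of 1. Shares of spots and of UMIs carried exact 95% binomial intervals. All these intervals cover counting error only, and leave out differences between people, biopsies, sections and library preparations.

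Gene lists (39) were fixed before the data were examined, as were the rule for named genes, the comparisons and most of the alternatives. There were 18 cell type lists: T cell, cytotoxic lymphocyte, B cell, plasma cell, resident macrophage, monocyte, lipid-associated macrophage, dendritic cell, neutrophil, mast cell, cardiomyocyte, fibroblast, activated fibroblast, endothelial cell, mural cell, adipocyte, Schwann cell and erythroid. The 21 pathway lists covered IL-1 signalling, the NF-kB response, the interferon gamma response, the type I interferon response, MHC class II, chemokines, T cell checkpoint and regulation, endothelial activation, complement, cardiac stress, oxidative phosphorylation, fatty acid oxidation, glycolysis, hypoxia, immediate early genes, heat shock, proliferation, the TGF-beta response, lysosome and phagocytosis, extracellular proteases and inhibitors, and mitochondrially encoded genes. For each list the median log2 ratio was taken over members with at least 20 UMIs in both sections together. Its 95% interval came from 1000 Poisson resamplings of the counts. Its percentile was taken among 10000 random lists of the same size, drawn for each member from the 100 genes nearest in mean CPM, and describes these 2 libraries. Members at least 1.5-fold higher or lower were counted. Lists of 12 glucocorticoid receptor target genes and 11 fasting target genes were added after the data were seen.

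Named genes followed a fixed rule. Among genes with at least 20 CPM in a section and at least 50 UMIs, the 12 highest and 12 lowest ratios were named. From each list up to 4 members with the most UMIs and up to 2 members with the largest change among those with at least 50 UMIs were eligible. IL1A, IL1B, IL1RN, IL1R1, IL1R2, IL1RAP, NLRP3 and IL6 were always named, and regions were described by up to 5 leading genes. Some genes that this rule allows are not reported here.

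Nonspecific probe signal was estimated after the data were seen, as the trimmed mean CPM (5% off each end) of 359 olfactory receptor genes, which heart muscle should lack. A second estimate used 104 keratin-associated protein and taste receptor genes. Connected groups of at least 20 in-tissue spots were treated as separate pieces of tissue; pieces of a section are not replicates of a treatment. For shares of spots with a marker UMI, every spot was thinned at random without replacement to 2500 UMIs, and shallower spots were left out (196 before, 33 after). Spatial clustering was described by Moran's I over neighbouring spots, and pairs of lists by Spearman's rho across spots, both on thinned counts within a section. Regions came from Leiden clustering of each section alone (2000 variable genes, 20 components, 15 neighbours, resolution 0.5).

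The alternatives chosen then were other minimums of UMIs per spot (none, 1000), tissue without its edge (spots with 6 in-tissue neighbours), median-of-ratios size factors, totals without cardiomyocyte, mitochondrially encoded and the 50 most abundant genes, the mean over spots of each spot's CPM, thinning to equal depth, subtraction of off-tissue counts, leaving out each piece in turn, other minimums of CPM (5, 50) and of UMIs per list member (none, 100), a prior of 2 counts, other thinning depths, unthinned counts for Moran's I, and resolution 1. Subtraction of the olfactory floor and random sets of olfactory genes as background for spot shares were added after the data were seen.

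The procedure was tested on simulated counts of the after over before comparison with 18447 genes, 200 of them changed. It recovered 99% of the genes set at 3-fold and 97% of those set at 4-fold, with 0 false calls. In separate simulated counts with no gene changed, 95.8% of the intervals of genes with at least 50 UMIs held the true ratio. The simulated counts carried counting error only. They held no difference in nonspecific signal and no pieces of tissue, so they say nothing about errors from those. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9.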

Results

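Gene expression was mapped in 2 sections of heart muscle biopsied through the vessels in lymphocytic myocarditis, an inflammation of the heart in which lymphocytes infiltrate the muscle. Of these, 1 was labelled as before and 1 as after rilonacept, a fusion protein that traps the cytokine interleukin-1 (IL-1). The labels used here do not state whether both sections came from the same person, and with 1 sample per group the difference between them had no replicate check. The before section held 797 usable spots with 6588138 UMIs, a median of 5783 UMIs and 2585 genes per spot. The after section was deeper, with 1277 spots, 17242111 UMIs and a median of 13795 UMIs and 4157 genes per spot. Mitochondrially encoded genes took 19.7% of UMIs before and 19.2% after, and the 50 most abundant genes 39.0% and 40.8%. The before spots formed 2 separate pieces of tissue, piece 1 with 489 spots and a median of 3073 UMIs, and piece 2 with 306 spots and 12729 UMIs. The after spots formed 5 pieces of 40 to 481 spots, with medians of 10284 to 15516 UMIs. Olfactory receptor genes, which heart muscle should lack, averaged 1.61 CPM before and 0.360 CPM after. This floor of nonspecific probe signal was therefore 4.48-fold higher before, and in before piece 1 it reached 2.98 CPM.

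The comparison of the 2 sections addresses how the immune cells of the heart differ between tissue before and after IL-1 blockade. Genes induced by interferon gamma, the main macrophage-activating cytokine of T cells, were lower after rilonacept. CXCL10, a chemokine that draws activated T cells into tissue, stood at 26.6 CPM before and 0.870 CPM after, 29.6-fold lower (95% interval 18.01 to 55.7). CXCL9, a chemokine for the same receptor, was 5.34-fold lower (4.10 to 7.04). GBP1, an interferon-induced GTPase that acts against intracellular microbes, was 5.15-fold lower, and IRF1, a transcription factor of the interferon response, 4.46-fold lower. These genes were high in 1 of the 2 before pieces. CXCL10 stood at 66.7 CPM in before piece 1, at 1.72 CPM in before piece 2 and at 1.13 CPM or less in each after piece. All 17 measured members of the interferon gamma response list were at least 1.5-fold lower after, among them TAP1, the peptide transporter of antigen presentation (78.6 to 25.6 CPM). The list's median log2 ratio was −1.85 (−2.10 to −1.63), against −0.26 for the median of random lists of matched expression, at percentile 0 of 10000 such lists. Without before piece 1 it was −0.18, at percentile 30.3. The list took 1151 CPM in before piece 1, 201 in before piece 2 and 162 to 256 in the after pieces, as the maps of this list show.

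**Figure D1:**
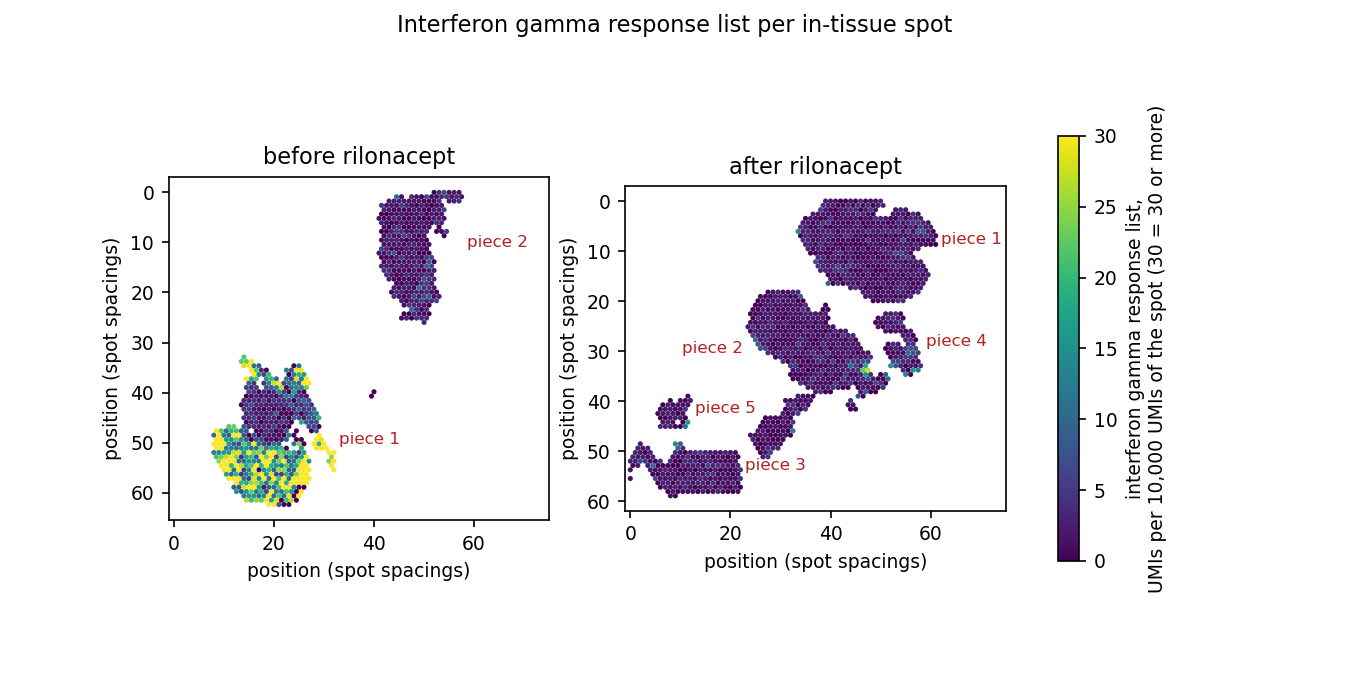
Each dot is an in-tissue spot of the before (left) or after (right) section at its position in spot spacings, coloured by the UMIs of the interferon gamma response list per 10000 UMIs of the spot, with values of 30 or more in yellow. High values fill the lower part and the upper rim of before piece 1 (1151 CPM over the piece), while before piece 2 (201) and the 5 after pieces (162 to 256) stay low.

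Other interferon and antigen presentation genes, summed by list, were also highest in before piece 1. The type I interferon response list took 900 CPM there, 425 in before piece 2 and 350 to 449 in the after pieces. In the type I interferon response list 12 of 18 members were at least 1.5-fold lower after and 0 higher, with a median log2 ratio of −0.65 (percentile 0). IFIT3, an interferon-induced inhibitor of viral translation, stood at 46.3 CPM before and 18.8 CPM after, whereas IFI27 stood at 78.3 and 74.9 CPM. Of the 9 genes of the MHC class II list only CD74, the chaperone of class II molecules, gave counts. Whether the probes cover the other members is not known, so their lack of counts says nothing about their expression. The log2 ratio of CD74 was −0.83, with 401 CPM in before piece 1, 118 CPM in before piece 2 and 48.8 to 137 CPM in the after pieces. PLAAT4, a retinoid-inducible phospholipase, was 7.04-fold lower after (6.02 to 8.27), with 214 CPM in before piece 1 and 11.8 CPM in before piece 2. Among chemokines, 11 of 16 members were lower and 1 was higher, with a median of −1.82 (percentile 0.2). CCL19, which guides T cells and dendritic cells in lymphoid tissue, was 30.5-fold lower after (16.8 to 68.3) and stood at 46.8 CPM in before piece 1 and 0.983 CPM in before piece 2. CCL21, for the same receptor, stood at 17.9 and 15.5 CPM in the before pieces and at 1.13 to 7.04 CPM in the after pieces. With before piece 1 left out the medians were −0.17 for the type I interferon response, 0.10 for CD74 and 0.09 for chemokines.

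IL-1 itself was captured too rarely to compare. IL1B gave 15 UMIs before and 11 after (2.28 and 0.638 CPM) and IL1A gave 12 and 12, levels within 2-fold of the floor of each section, so the higher floor before leaves their difference open. The receptor antagonist IL1RN gave 11 and 5 UMIs, the decoy receptor IL1R2 8 and 17, and the inflammasome sensor NLRP3 20 and 23. The signalling receptor IL1R1 stood at 26.9 CPM before and 25.4 CPM after, a ratio of 0.944 (0.792 to 1.13), and its partner IL1RAP at 14.9 and 12.4 CPM. In the IL-1 signalling list 11 of 21 members were at least 1.5-fold lower after and 0 higher. Its median of −0.63 (−0.85 to −0.41) lay at percentile 31.2 of matched random lists, among other genes of its abundance. It was 0.06 at percentile 96.7 without before piece 1 and −1.55 at percentile 0.77 without before piece 2. CASP1, the protease that matures IL-1, stood at 15.5 and 9.34 CPM in the before pieces and at 0 to 5.81 CPM in the after pieces. GSDMD, which forms the membrane pore that releases IL-1, stood at 68.9 CPM before and 32.2 CPM after.

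Targets of NF-kB, the transcription factor that IL-1 and other inflammatory signals activate, were lower after. In this list 14 of 21 members were at least 1.5-fold lower and 0 higher, with a median of −1.48 (−1.63 to −1.21) at percentile 0; without before piece 1 it was −0.46, at percentile 0.2. The monocyte chemokine CCL2 stood at 17.9 CPM before and 2.84 CPM after, the adhesion molecule ICAM1 at 24.6 and 5.63 CPM, and the cytokine IL6 at 4.71 and 0.812 CPM (31 and 14 UMIs). The early response gene IER3 was lower in each after piece (18.1 to 31.5 CPM) than in both before pieces (63.5 and 70.0 CPM). The most abundant members differed little, with SOD2 at 695 CPM before and 765 CPM after and NFKBIA at 74.1 and 70.3 CPM. For endothelial activation 8 of 9 members were lower, with a median of −0.96 at percentile 5.53. VCAM1, a leukocyte adhesion molecule of this list, stood at 12.8 and 5.97 CPM, and without before piece 1 the list's median was 0.01. In the complement list 6 of 13 members were lower, with a median of −0.57 at percentile 0.42 and 0.10 without before piece 1. Its central component C3 stood at 104 CPM before and 54.9 CPM after.

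Antibody genes showed the largest difference of any immune cell list. IGKC, the kappa light chain constant region, was 7.64-fold lower after (7.36 to 7.93), and IGHG1, the IgG1 heavy chain constant region, 8.85-fold lower (8.26 to 9.49). IGKC stood at 4263 CPM in before piece 1, at 7.37 CPM in before piece 2 and at 1.88 to 281 CPM in the after pieces. Heavy chain constant genes resemble each other in sequence, and how far the probes separate them was not tested. In the plasma cell list 10 of 11 members were lower, with a median of −2.36 at percentile 0, and without before piece 1 it was 2.30. Genes of cytotoxic lymphocytes were also lower in 14 of 16 members, with a median of −1.52 (−1.70 to −1.11) at percentile 3.78. GNLY, a pore-forming granule protein, stood at 16.5 CPM before and 4.06 CPM after, and GZMB, a granule protease, at 6.83 and 1.04 CPM, while the receptor gene KLRD1 stood at 7.29 and 9.40 CPM. Without before piece 1 the cytotoxic median was 0.24.

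The T cell list was lower after in 14 of 22 members, with a median of −0.77 (−1.07 to −0.58), but random lists of matched expression had a median of −1.07, and the T cell list lay at percentile 93.0 among them. Less the floor, it took 69.6 CPM before and 55.1 after. TRAC, the constant region of the T cell receptor alpha chain, stood at 9.87 CPM before and 8.35 CPM after, a ratio of 0.843 (0.627 to 1.15), and the survival receptor IL7R at 5.62 and 7.25 CPM. The kinase ZAP70, which transmits the T cell receptor signal, stood at 11.2 and 3.94 CPM, and the costimulatory receptor CD28 at 5.62 and 1.86 CPM. The list took 221 CPM in before piece 1, 33.4 in before piece 2 and 25.7 to 91.9 in the after pieces. With before piece 1 left out its median was 0.72, above all 10000 random lists (percentile 100), and without before piece 2 it was −1.88. The T cell checkpoint and regulation list had 7 of 13 members lower and a median of −0.88 at percentile 47.5. PDCD1, the inhibitory receptor PD-1, stood at 7.13 and 1.74 CPM, and without before piece 1 the list's median was −0.15.

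Resident macrophage genes were lower in 7 of 16 members and higher in 1, with a median of −0.48 (−0.67 to −0.40) at percentile 5.19. The scavenger receptor CD163 stood at 38.6 CPM before and 28.8 CPM after, and the complement gene C1QB at 20.8 and 9.16 CPM. In before piece 2 CD163 stood at 10.3 CPM, below the 25.6 to 34.3 CPM of the after pieces. Monocyte genes were lower in 10 of 14 members, with a median of −0.86 (−1.20 to −0.62) at percentile 36.7. LYZ, lysozyme, stood at 45.2 and 15.7 CPM and VCAN, versican, at 35.5 and 35.0 CPM. Without before piece 1 the medians were 0.68 for resident macrophages and 0.51 for monocytes, both at percentile 100. Lipid-associated macrophage genes had a median of −0.04 (−0.15 to 0.06) at percentile 98.6, a sign that became positive (0.16) with median-of-ratios size factors and 0.39 without before piece 1. SPP1, osteopontin, stood at 8.50 CPM before and 20.4 CPM after, and at 226 CPM in after piece 4.

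The lists of the scarcest immune cells lay among random lists of matched expression over the whole sections. Medians were −1.86 for B cells (7 of 7 members lower, percentile 31.1), −1.68 for dendritic cells (8 of 8, percentile 16.3), −1.49 for neutrophils (5 of 7, percentile 66.6) and −1.74 for mast cells (4 of 5, percentile 30.2). Most members of these lists gave few UMIs. Among the more abundant ones, CD79B of the B cell receptor stood at 8.35 CPM before and 5.57 CPM after, and IRF8, a dendritic cell transcription factor, at 17.5 and 4.52 CPM. GATA2, a transcription factor of mast cells and endothelium, stood at 16.5 and 16.5 CPM, and MME, a neutrophil surface protease also made by stromal cells, at 10.2 and 12.8 CPM. With before piece 1 left out the medians were −1.19, 0.15, 0.24 and −1.05 for these 4 lists, over at most 5 members each. Leaving out before piece 2 put the dendritic cell list at −2.74 and percentile 0.43; less the floor it took 54.7 CPM in before piece 1, 10.1 in before piece 2 and 7.85 to 11.99 in the after pieces.

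**Figure D2:**
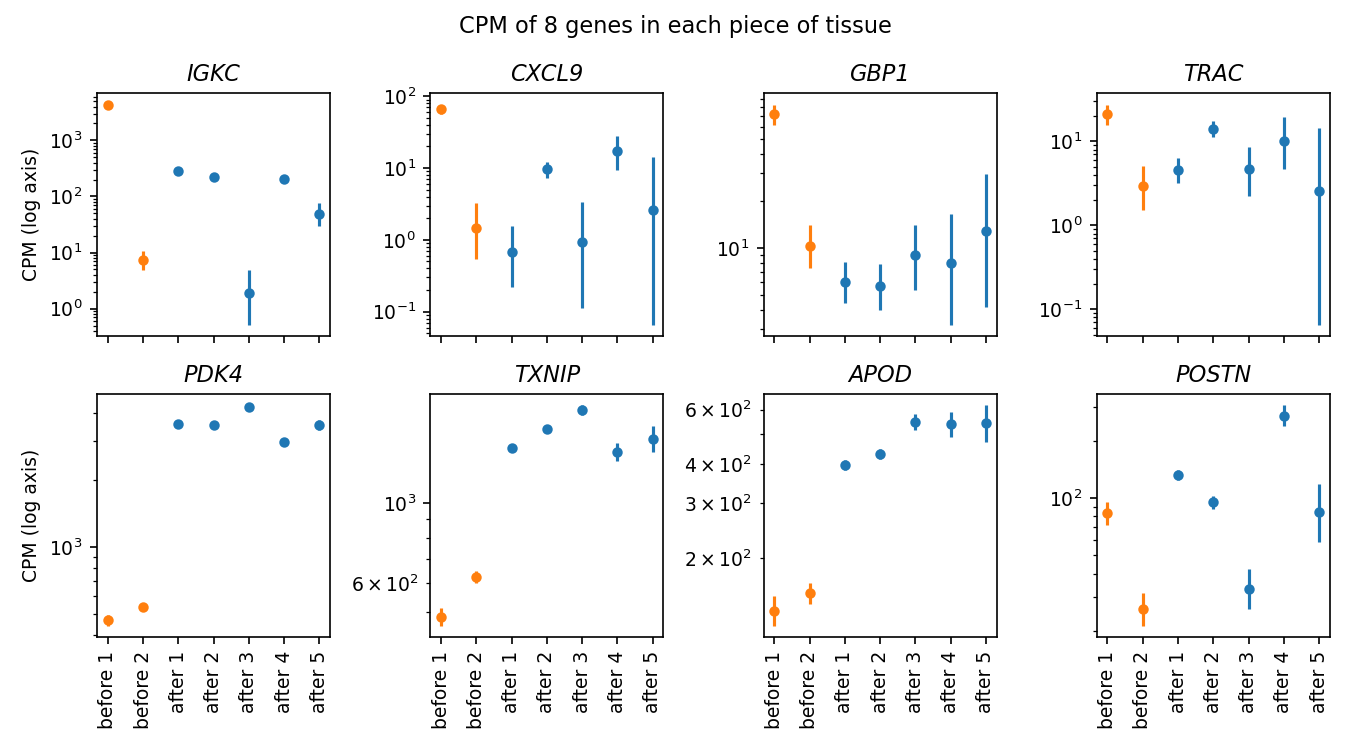
CPM on a log axis of 8 genes in each piece of the before (orange) and after (blue) sections; bars are exact 95% Poisson intervals covering counting error only. IGKC, CXCL9, GBP1 and TRAC were highest in before piece 1 (4263, 65.9, 71.9 and 21.04 CPM), whereas PDK4, TXNIP and APOD were higher in each after piece than in both before pieces.

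Shares of spots with a marker UMI were compared at 2500 UMIs per spot. T cell UMIs were found in 24.4% of 610 before spots (21.1 to 28.0%) and 11.9% of 1244 after spots (10.1 to 13.8%). Sets of as many olfactory genes were found in 10.9% and 2.09%, so part of the before share was background. Unthinned shares were 43.9% and 39.2%. In before piece 1 the T cell share was 41.0%, in before piece 2 7.87%, and in the after pieces 8.11 to 16.9%. Olfactory sets of that size were found in 16.8%, 5.02% and 1.66 to 3.28% of these spots. The background thus differed by piece, and most of the share in before piece 2 can be background. Cytotoxic lymphocyte UMIs were found in 23.3% and 9.65% of spots, resident macrophage UMIs in 50.7% and 41.3%, and monocyte UMIs in 35.2% and 24.1%. Their olfactory sets were found in 8.81% and 1.60%, 8.26% and 1.51%, and 7.79% and 1.42%, so background took part in these gaps too. B cell UMIs were found in 7.54% and 2.49% of spots, against 6.28% and 1.16% for olfactory sets. The adipocyte and erythroid lists were found in 71.6% and 69.0% and in 23.9% and 27.3% of spots. At 5783 UMIs per spot, which leaves out most spots of the shallow before piece 1, the ratio of the T cell share, after over before, turned from 0.487 to 1.13 and that of the monocyte share from 0.684 to 1.10.

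Among genes with at least 20 CPM in a section and at least 50 UMIs the highest ratio was that of PDK4. PDK4 is a kinase that inhibits pyruvate dehydrogenase and favours fatty acid use. It stood at 509 CPM before and 3611 CPM after, 7.09-fold higher (6.85 to 7.34). It stood at 468 and 535 CPM in the before pieces and at 2959 to 4272 CPM in the after pieces. TXNIP and ARRDC4, related arrestin-domain proteins that restrain glucose uptake, were 2.68-fold (2.59 to 2.78) and 3.06-fold (2.52 to 3.77) higher, likewise with each after piece above both before pieces. The lipid-binding lipocalin APOD stood at 135 and 154 CPM in the before pieces and at 398 to 548 CPM in the after pieces. The fatty acid oxidation list as a whole had a median of 0.09 at percentile 69.6, with PDK4 the 1 member at least 1.5-fold higher, so the difference lay in that gene and not in the list. Also among the 12 highest ratios were FCN3, a lectin that activates complement (8.20 to 29.2 CPM), CYP4B1, a cytochrome P450 (22.3 to 71.6 CPM), the catenin CTNND2 (6.22 to 23.8 CPM) and the lipocalin LCN6 (10.3 to 28.8 CPM).

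Some connective tissue genes were higher after, and the direction of their lists depended on the piece. In the activated fibroblast list 8 of 20 members were at least 1.5-fold higher and 3 lower, with a median of 0.44 (0.33 to 0.57) at percentile 100. POSTN, periostin, a matrix protein of healing heart muscle, stood at 48.0 CPM before and 112 CPM after, and fibronectin, FN1, at 153 and 272 CPM, while the transcription factor RUNX1 stood at 15.3 and 6.21 CPM. The list took 1457 CPM in before piece 1, 473 in before piece 2 and 577 to 2271 in the after pieces. Its median was 1.43 without before piece 1, −0.42 without before piece 2 and −0.18 when each spot weighed the same. In the fibroblast list 4 of 14 members were higher and 0 lower, with a median of 0.30 at percentile 100, and the proteoglycan LUM stood at 120 and 226 CPM; without before pieces 1 and 2 in turn the median was 0.54 and −0.03. The TGF-beta response list had 3 of 14 members higher and a median of 0.06 at percentile 98.6, with 0.53 without before piece 1 and −0.36 without before piece 2. LTBP2, a matrix protein of this list, was 3.19-fold higher (2.89 to 3.54), and the matricellular growth factor CCN2 2.23-fold. SERPINE2, a protease inhibitor of the matrix, stood at 19.0 and 59.4 CPM and the bone proteoglycan OMD at 6.98 and 20.2 CPM.

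Cardiomyocyte genes differed little. Of 19 measured members 0 were 1.5-fold higher or lower, with a median of 0.12 (0.11 to 0.13) at percentile 36.2, and the list took 135346 CPM before and 143100 after. By piece the list took 105450 CPM in before piece 1, 153868 in before piece 2 and 126653 to 146821 in the after pieces. Without before piece 1 the median was −0.03. MYH7, the beta myosin heavy chain, stood at 18002 and 20537 CPM, and MYL2, ventricular myosin light chain, at 25473 and 24843 CPM. In the cardiac stress list 2 of 14 members were higher, with a median of 0.32 (0.29 to 0.34) at percentile 99.9. These were NPPB, which encodes the natriuretic peptide BNP (721 to 1255 CPM), and ANKRD1, a stretch-responsive repressor (2939 to 5114 CPM). NPPB varied widely between pieces, from 591 to 931 CPM before and from 130 to 1781 CPM after. The median of the cardiac stress list was 0.21 without before piece 1 and 0.70 without before piece 2. Energy metabolism lists lay near 0, with medians of 0.05 for oxidative phosphorylation, −0.07 for glycolysis and −0.10 for mitochondrially encoded genes. The last 2 turned positive with median-of-ratios size factors (0.13 and 0.10) and stayed negative without either before piece. Oxidative phosphorylation was −0.08 without before piece 1 and 0.25 without before piece 2. COX7A1, a muscle subunit of cytochrome oxidase, stood at 3234 and 3103 CPM, PFKM, muscle phosphofructokinase, at 544 and 509 CPM, and MT-CO1 at 29757 and 31455 CPM.

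**Figure D3:**
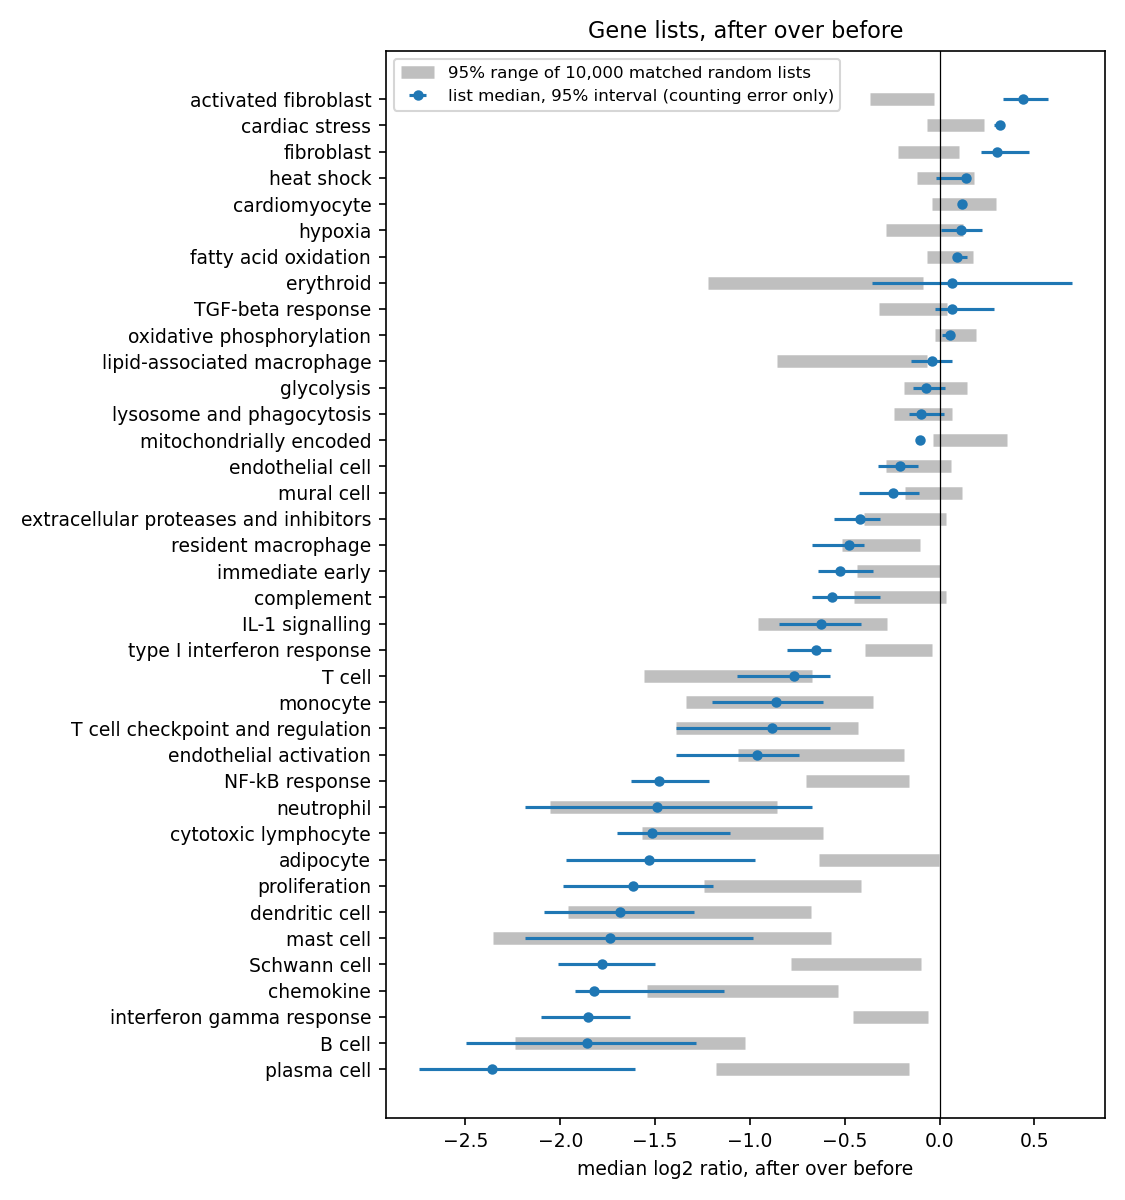
Median log2 ratio, after over before, of each gene list with at least 5 measured members (points), with 95% intervals covering counting error only (lines), beside the 95% range of 10000 random lists of matched expression (grey bars). The interferon gamma response (−1.85), plasma cell (−2.36) and NF-kB response (−1.48) lists lie below their grey bars, and the activated fibroblast list (0.44) lies above its bar.

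Among 7357 genes with at least 20 CPM in a section, 30 were at least 2-fold higher and 91 at least 2-fold lower after. With median-of-ratios size factors, which moved all genes up by 0.20 log2, the split was 62 higher and 55 lower. Genes lower numbered 157 with totals without abundant genes, 446 thinned to equal depth and 763 with each spot weighing the same, against 44, 42 and 27 higher. The split rested on the pieces too, with 72 higher and 24 lower without before piece 1. Without before piece 2 it was 30 higher and 627 lower. Of the 91 lower genes, 54 were lower in each after piece than in both before pieces. Of the 30 higher genes, 19 were higher in each after piece than in both before pieces. These genes were chosen by their ratio over the same pieces, so such agreement is partly built in. The olfactory floor separated the same way as the lower genes, at 2.98 and 0.755 CPM before and 0.277 to 0.488 CPM after. The same count over all 7357 genes was not made.

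Within the before section, muscle and immune genes each lay together. Moran's I at equal depth was 0.709 for the cardiomyocyte list, 0.753 for the plasma cell list, 0.508 for the interferon gamma response, 0.441 for resident macrophages and 0.366 for T cells, against 0.0571 for olfactory sets. After rilonacept these were 0.465, 0.216, 0.105, 0.181 and 0.231, against 0.00947. The plasma cell values depended on thinning, with 0.746 before and 0.682 after on unthinned log-normalized counts, where resident macrophages gave 0.446 and 0.322 and T cells 0.447 and 0.361. Across before spots the T cell list went with the interferon gamma response list (Spearman's rho 0.481), and the latter went against the cardiomyocyte list (−0.636). In the after section these were 0.0454 and −0.113; spots are not independent, so no p-value is given. The thinned counts were sparser after, with 216 T cell and 637 interferon gamma response UMIs over 1244 spots. Before, these were 246 and 1319 over 610 spots. The before values also pool pieces of unlike level, with 1151 CPM for the interferon gamma response in piece 1 and 201 in the other. Lower rho or Moran's I after therefore need not mean that the lists lay together less. Clustering gave 5 regions before. A region of 261 spots, all in piece 1, was led by GBP5, CXCL10, IL4I1, PLAAT4 and CXCL9, and its spots took 2400 CPM for the interferon gamma response and 548 for T cells. A region of 138 spots was led by the smooth muscle genes MYH11, ITGA8, ACTA2 and MYLK with IGHG1, and took 10146 CPM for the plasma cell list. A region of 19 spots was led by the fat genes PLIN1, ADIPOQ, FASN, GPAM and FABP4, and regions of 272 and 107 spots by HBB and by NPPB. After rilonacept 6 regions were found. A region of 246 spots was led by IGHM, IGHG2, CXCL9, SPP1 and IL7R and took 155 CPM for T cells, 273 for the interferon gamma response and 2580 for activated fibroblasts. The others were led by CTNND2 (375 spots), haemoglobin genes (328), MYH11 (226), SCD (88) and PPBP (14).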

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

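Of the tests below, those of the interferon gamma response list with the floor subtracted and without before piece 1, that of the T cell list and that of the cardiomyocyte share were chosen only after the result was seen, although leaving out each piece was an alternative fixed earlier.

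Spots outside the tissue, which no comparison in the report uses, carried signal. They held 7.89% of all UMIs before and 7.68% after, of which 84.5% and 88.7% lay within 2 spots of the tissue. IGKC, the antibody kappa chain, gave 838 UMIs outside the tissue before and 565 after, and CXCL10 gave 35 before and 0 after. Both are genes of the inflamed before piece. Subtracting the mean count outside the tissue left the medians of the 8 lists it was run for within their intervals, and the counts of genes at least 2-fold higher and lower at 29 and 91.

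Higher nonspecific signal before, as estimated by the mean olfactory floor, does not account for the lower interferon gamma response list after. Its median was still −1.84 with that floor subtracted. A mean over the section understates the floor of before piece 1, but that piece's own floor came to 50.7 of the list's 1151 CPM there. Low depth in before piece 1 does not account for it either: in the third of that piece's spots with the most UMIs, the list's share less its floor was 3.90-fold that of the after section. Without before piece 1 the median was −0.175, so the difference rested on 1 inflamed piece of the 2. Whether the tissue after treatment lost such areas or the biopsy missed them stays open, as does the effect of treatment, which was not tested. The lower T cell list (percentile 93.0) may owe part of its median to nonspecific signal, but less the floor it too was highest in before piece 1, at 155 CPM against 16.8 in before piece 2 and 19.6 to 84.4 after.

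PDK4, TXNIP and ARRDC4 were higher in each after piece than in both before pieces. A larger share of cardiomyocyte RNA does not explain this, because that share was 1.06-fold, nor does a single deviating piece, because PDK4 stood at 468 and 535 CPM in the before pieces and at 2959 to 4272 CPM in the after pieces. The median of the 3 genes with any 1 piece left out, at lowest 1.56, only restates this, since they were chosen for high ratios. Glucocorticoid receptor activity and fasting metabolism, with target list medians of 0.31 and 0.13, cannot be told apart from other causes, as the other observations describe. Handling of the biopsies and differences between people are confounded with the groups, and the effect of treatment was not tested.

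The 2382 genes at 1 to 2 CPM had a median log2 ratio of −1.82. Higher nonspecific probe signal before is a candidate explanation, since keratin-associated protein and taste receptor genes were 4.58-fold higher before, close to the 4.48-fold of olfactory receptor genes. Subtracting the mean floor still left −1.24, so a single mean does not remove it. Fewer UMIs per spot before cannot be told apart from this: thinning to equal depth (−2.11) keeps each gene's expected share of UMIs, and in before piece 1 the floor was 8.11, 5.97 and 1.32 CPM in 3 sets of 163 spots with medians of 1567, 3073 and 9301 UMIs. No biological explanation was tested.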

How the results depend on the processing

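Subtraction of the olfactory floor was chosen only after the data were seen, as a test of background; the other alternatives were planned. Where values below differ from those in the report the cause was not tested, except for minimums of CPM and for list medians under 2 other scalings. A lower minimum of CPM counts more genes and a higher one fewer. Median-of-ratios size factors moved the log2 ratio of every gene up by 0.20, and totals without abundant genes by 0.047. The lists of T cells, cytotoxic lymphocytes, resident macrophages, monocytes, activated fibroblasts, cardiomyocytes, IL-1 signalling and the interferon gamma response had medians of −0.77, −1.52, −0.48, −0.86, 0.44, 0.12, −0.63 and −1.85. Leaving out each piece in turn gave, in the same order, −1.88 to 0.72, −2.35 to 0.24, −1.47 to 0.68, −2.07 to 0.51, −0.42 to 1.43, −0.027 to 0.36, −1.55 to 0.0598 and −2.78 to −0.18. Of these 8 lists only the interferon gamma response kept its sign, and each reversal came from leaving out a before piece. With each spot weighing the same the medians were −1.77, −2.39, −1.39, −1.91, −0.18 (reversed), 0.40, −1.41 and −2.81. With median-of-ratios size factors the T cell, resident macrophage, activated fibroblast and cardiomyocyte medians were −0.57, −0.28, 0.64 and 0.32. Totals without abundant genes gave 0.17 for cardiomyocytes. Thinned to equal depth, cytotoxic lymphocytes gave −1.97, resident macrophages −0.84, monocytes −0.30, activated fibroblasts 0.29, cardiomyocytes 0.24 and the interferon gamma response −2.29. Without the tissue edge monocytes gave −1.35 and cardiomyocytes 0.13. With the floor subtracted T cells, monocytes and IL-1 signalling gave −0.41, −0.59 and −0.32, and with members of at least 100 UMIs −0.51, −0.54 and −0.39. Genes at least 2-fold higher numbered 30; with median-of-ratios 62, at a minimum of 5 CPM 47, at 50 CPM 17, and with pieces left out 30 to 72. Genes at least 2-fold lower numbered 91; with median-of-ratios 55, with totals without abundant genes 157, with each spot weighing the same 763, thinned 446, at 5 CPM 839, at 50 CPM 18, and with pieces left out 24 to 627. Ratios of spot shares, after over before, were 0.487 for T cells, 0.414 for cytotoxic lymphocytes, 0.816 for resident macrophages and 0.684 for monocytes. Thinned to 1250 UMIs per spot T cells gave 0.359, resident macrophages 0.625 and monocytes 0.443. At 5783 UMIs, where shallow spots of before piece 1 drop out, T cells gave 1.13 (reversed), cytotoxic lymphocytes 0.692, resident macrophages 0.974 and monocytes 1.10 (reversed). In all, 69 of 112 alternative values of these list medians lay within the interval of the reported value, 35 moved in the same direction and 8 reversed. Of 18 values of Moran's I, 10 differed by less than 0.1 with unthinned counts and 8 by more, among them the plasma cell list after (0.216 to 0.682). At resolution 1 clustering gave 8 regions before and 9 after, in place of 5 and 6. No paired analysis was possible with 1 sample per group, and the labels do not link the 2 sections to 1 person. Depth limits scarce genes most: most members of the B cell, dendritic cell, neutrophil and mast cell lists gave few UMIs in either section.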

Other observations

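The glucocorticoid receptor and fasting target lists were chosen as tests only after PDK4 had been seen to be higher, and their results were not known when the tests were written.

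Some genes of smooth muscle, fat and nerve were lower after. MYH11, smooth muscle myosin, stood at 130 and 129 CPM in the before pieces and at 6.80 to 100.04 CPM in the after pieces, and ACTA2, smooth muscle actin, at 86.8 CPM before and 33.4 CPM after. CNN1, calponin of smooth muscle, stood at 109 and 136 CPM and RGS5, a pericyte gene of the same mural cell list, at 290 and 460 CPM. The list's median was −0.24 (4 of 12 members lower, 1 higher, percentile 0.55), and without before piece 1 −0.06 at percentile 20.7. The adipocyte list had 6 of 10 members lower and a median of −1.53 at percentile 0. ADIPOQ, adiponectin, was 5.85-fold lower (4.40 to 7.90) and PLIN1, a coat protein of lipid droplets, 5.32-fold lower; both were highest in before piece 1 (44.5 and 47.6 CPM), and without that piece the list's median was −0.14. The more abundant AQP7, a glycerol channel, stood at 126 and 139 CPM. In the Schwann cell list 7 of 8 members were lower, with a median of −1.78 at percentile 0 and −1.39 without before piece 1. S100B, a glial calcium-binding protein, was 4.69-fold lower. TAF11L3, a gene related to a general transcription factor, was 4.56-fold lower.

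Vessel and blood genes varied. The endothelial list had a median of −0.21 at percentile 11.6, with VWF at 240 CPM before and 353 CPM after and CLDN5, a tight junction protein, at 43.9 and 22.97 CPM. In the erythroid list 3 of 8 members were higher and 3 lower, with a median of 0.07 (−0.35 to 0.70) at percentile 99.7. It was 1.48 with the floor subtracted and 1.61 without before piece 1, and the list took 160 CPM before and 406 CPM after. HBA2, alpha globin, stood at 24.9 to 652 CPM across the after pieces and at 87.3 and 53.8 CPM in the before pieces, which can reflect blood held in the tissue; its sequence nearly equals that of HBA1, so the 2 are not told apart with certainty.

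Further lists had medians of −0.52 for immediate early genes (7 of 17 members lower, percentile 0.45; 0.14 without before piece 1), −1.62 for proliferation (11 of 16 lower, percentile 0.09), 0.11 for hypoxia (−0.27 without before piece 2), 0.14 for heat shock, −0.42 for extracellular proteases and inhibitors and −0.10 for lysosome and phagocytosis, the last positive (0.10) with median-of-ratios size factors. Leaving out before piece 1 gave −0.0197 for heat shock, −0.14 for proteases, 0.30 for lysosome and −0.95 for proliferation. JUNB, an early growth response gene, stood at 98.5 CPM before and 62.9 CPM after, and TOP2A, a topoisomerase of dividing cells, at 6.22 and 0.870 CPM. TIMP3, a metalloproteinase inhibitor, stood at 346 and 639 CPM, HIF3A, a hypoxia-inducible factor, at 96.8 and 149 CPM, HSPA8, a constitutive chaperone, at 317 and 418 CPM, and CTSB, cathepsin B, at 421 and 517 CPM.

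PDK4 and ANGPTL4 are induced both by glucocorticoids and by fasting, so higher PDK4 may come from either. The list of 12 glucocorticoid receptor target genes had a median of 0.31 (0.19 to 0.35) at percentile 100, with MT1X (0.99) and MAOA (0.94) the 2 members at least 1.5-fold higher. The list of 11 fasting target genes had a median of 0.13 (0.07 to 0.21) at percentile 99.1, and among its members ANGPTL4 (1.16) was higher and ACOT1 (−1.39) lower. These shifts are small beside that of PDK4 and their members differ, so the 2 lists decide for neither.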
